A study of Mus musculus with 94 samples.

How the data were processed

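The series held 94 Agilent 2-colour arrays of design 014868, each with liver RNA labelled with Cy5 and a common reference of pooled organ RNA labelled with Cy3. No array had the dyes exchanged, so any bias of a probe towards a dye is the same on each array and leaves differences between arrays as they are. Per the file headers, the authors extracted the scans with Agilent Feature Extraction 9.5.1.1, and 3 arrays used another version of its protocol. The files hold the mean pixel intensity of each spot and its median local background in both channels, neither subtracted nor normalised, per the file headers. They also hold, per the file headers, a processed log10 ratio of Cy5 over Cy3 with background subtracted and dyes normalised, and flags of 0 or 1 for saturation, outlying spots and signal well above background. A further table of deposited values gives a log2 ratio per array for 25617 probes, and how the authors normalised, filtered or adjusted it for batch is not stated.

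The tests used the spot intensity. Control spots (1639) were left out, and the 43379 remaining spots gave 41174 probes. Background was subtracted with the normexp method of limma 3.58.1 (R 4.3.3, offset 50), ratios were normalised within each array by loess, and replicate spots of a probe were averaged after outlying spots (0.374%) were removed. The loess step sets the bulk of genes on an array to no difference, so a change shared by most genes would be taken out. The offset pulls ratios of dim spots towards 0, so large differences near background are understated. Gene symbols came from the reference table through the probe's accession (22951 probes), from the symbol in the file (9768 probes) or from the file's name alone (8455 probes). No genome build or probe position came with the files, so no coordinates are given. A probe was kept if its Cy5 signal was well above background on each array of at least 1 group (29671 probes, of which 364 with missing values were left out). The probe of highest mean intensity stood for each gene, which gave 19872 genes. Several probes were present for 6723 genes, and in 2458 of these they differed in the sign of the averaged effect. Tables were read with data.table (version 1.17.8) and jsonlite (version 2.0.0).

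Groups followed the labels: 16 strains with TCE or vehicle, 32 groups of 2 to 4 arrays. The labels do not say whether the arrays of a group came from separate mice, so the p-values measure the spread between these arrays. The labelled batch (6 levels) entered each fit as a fixed block, since treatment and batch overlapped within most strains. The offsets of the batches were estimated from the groups that span several batches. In the residuals of a fit without it, over pairs from different groups and leaving out BALB/cByJ vehicle replicate 2, arrays of the same batch correlated at 0.152 on average and arrays of different batches at -0.029, which is why the block was kept. Limma's lmFit and eBayes gave 57 residual degrees of freedom and a prior worth 3.6. Log-scale effects are differences of fitted group means with their SE, and p-values are two-sided and adjusted by Benjamini-Hochberg at a threshold of 0.05. A fold against a group whose arrays lie at background is given as a lower bound.

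The comparisons were the TCE effect averaged over strains with equal weight, an F test over the 15 differences of that effect between strains, and an F test over vehicle groups. TCE was also set against vehicle within each strain, and shifts of gene lists were tested. The 33 lists (723 genes, at least 5 of them measured in each) cover pathways of fatty acid oxidation, xenobiotic response, stress, lipid, amino acid and clock genes. They also cover sex-biased liver genes, and markers of liver cell types, blood cells, fat and pancreas. They were tested with camera at a preset correlation between genes of 0.01 and, beside it, with an estimated correlation, and the list mean per array was tested for strain dependence with limma. Each array was compared with the mean profile of every strain over the 500 genes with the largest F among the labelled strains, after batch effects were removed. All 94 were closest to their own strain. An array was left out of its strain's mean, but not of the choice of genes or the batch fit, which can favour the labelled strain. The named genes followed a rule. It took the 12 largest rises and 12 largest falls among genes called in the averaged test with the same sign in at least 13 strains, the 20 called genes with the largest SD of strain effects, and the 20 with the largest SD of vehicle means. It also took up to 4 members of each list by smallest p, the largest rise and fall among called genes of each strain, and genes fixed beforehand, among them Cyp2e1, Ppara, Cyp4a10, Cyp4a14, Cyp2b10, Cyp7a1, Cdkn1a and Mki67. Probes without a symbol, gene models named by number and genes whose probes differ in sign were left out of the naming. These lists, tests, the naming rule and all alternatives but 3 were chosen before the data were examined.

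The alternatives were a fit without the batch block, slide as a random block (correlation 0.0385), the Agilent processed ratio, no background subtraction, median centring of each array, scaling between arrays, Cy5 alone with quantile normalisation, the deposited value table, no detection filter, detection on at least 90% of arrays, all detected probes, and array weights. Others were a 1.5-fold minimum, an additive model, fits within batches, and fits without 1 array, 1 strain, either batch 5 DBA/2J TCE array, the 3 arrays of the other protocol or the 3 wild-derived strains. The 3 added later left out BALB/cByJ vehicle replicate 2 together with the batch block, the 4 arrays of largest residual spread, and BALB/cByJ vehicle replicate 2 with 6 columns of the value table. Tested on simulated data, the averaged fit called 99.5% of genes changed 1.5-fold in each strain, with 4.04% false calls. The strain dependence test called 46% of genes changed 2-fold in 1 strain and 91.5% of those changed 4-fold, with 6.14% false calls, and the fit within FVB/NJ called 80% and 99.5% of such genes. The simulated noise was independent between genes and between arrays. On the real arrays shuffled treatment labels gave up to 759 strain-dependent genes. The false call rates of the simulation therefore need not hold for the real data. Median Cy5 intensity ranged from 454 to 1596 per array and median Cy3 intensity from 554 to 1098, and 4 to 157 spots per array were saturated in Cy5.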

Results

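Trichloroethylene (TCE) is a chlorinated industrial solvent. Liver RNA of fed male mice aged 7 to 9 weeks was measured 24 h after a gavage of 2100 mg/kg TCE in corn oil, or of corn oil alone at 10 ml/kg, in 16 strains. They included B6C3F1/J, the hybrid of C57BL/6J and C3H/HeJ, and 3 wild-derived strains, CAST/EiJ, MOLF/EiJ and PWD/PhJ. Each of 94 arrays carried liver RNA in the Cy5 channel and a pool of RNA from several organs of male C57BL/6J in the Cy3 channel, so a level below is a log2 ratio of liver over that pool. The 48 TCE and 46 vehicle arrays formed 32 groups: 28 groups of 3 arrays, 3 groups of 2 (A/J with TCE, C57BL/6J and KK/HIJ with vehicle) and 1 group of 4 (DBA/2J with TCE). Batch 5 held 2 arrays titled as DBA/2J TCE, replicates 2 and 3, and none titled as A/J TCE, and whether 1 of them is an extra animal is not stated. Both were closest to DBA/2J and were kept as titled. The share of Cy5 spots well above their background ranged from 42.4% to 79.5% per array (median 65.4%), and the number of arrays limits the precision of every value. The arrays came in 6 batches, and in 8 strains the TCE arrays lay mostly in batches 1 to 3 while in the other 8 they lay mostly in batches 4 to 6. BALB/cByJ vehicle replicate 2 stood apart from the rest. Its median correlation with other arrays was 0.414, against at least 0.771 for each of the other 93. Albumin (Alb) stood at -2.65 log2 on it, against 0.53 to 3.55 elsewhere. Each leading count is therefore also given without that array.

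The first comparison asked which genes TCE changed when the 16 strains were averaged with equal weight. Several of the strongest rises were in genes of fatty acid metabolism. Cyp4a14, a fatty acid omega-hydroxylase, rose by 2.75 log2 (SE 0.26, 94 arrays, adjusted p = 1.97e-11), a 6.73-fold change, and was higher in 14 of 16 strains. Its relative Cyp4a31 rose by 1.66 log2 (SE 0.16, 15 of 16 strains) and Cyp4a10 by 0.77 log2 (SE 0.09, 15 of 16 strains). Acot1 and Acot2, which release fatty acids from acyl-CoA, rose by 1.40 log2 (SE 0.13, 14 strains) and 0.83 log2 (SE 0.10, all 16 strains). The peroxisomal beta-oxidation enzymes Ehhadh and Acaa1b rose by 1.02 and 0.87 log2 (SE 0.09 and 0.10) in 15 and 14 strains.

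Among other genes that rose most were Acot3 (1.097 log2, SE 0.17), Serpina7, thyroxine-binding globulin (1.05 log2, SE 0.16), Vnn1, a pantetheinase (1.00 log2, SE 0.15), Gsta2, a glutathione transferase (0.89 log2, SE 0.11), and Spon2 (0.77 log2, SE 0.10). Rad51b also rose, by less than Acot1 and more than Acot3. Among the genes that fell most were Hsd3b4 and Hsd3b5, steroid dehydrogenases, at -0.81 log2 (SE 0.14, lower in 15 of 16 strains) and -0.70 log2 (SE 0.11, lower in 14). Slc22a7, an organic anion transporter, stood at -0.49 log2 (SE 0.08, lower in 15), and Lifr, a cytokine receptor, at -0.53 log2 (SE 0.10, lower in 14). Thrsp, a gene of lipid synthesis, stood at -0.65 log2 (SE 0.15, lower in 13) and Herpud1, of protein degradation at the endoplasmic reticulum, at -0.47 log2 (SE 0.08, lower in 15). Nat8, Gna14, Mpv17l and Tcim fell by 0.46 to 0.50 log2. Noct and Nudt7 passed narrowly (-0.48 and -0.46 log2, adjusted p = 0.0449 and 0.0414), and leaving out 1 array ended their calls in 51 and 32 of 94 fits. Ppara itself, the nuclear receptor of fatty acids, showed -0.0022 log2 (SE 0.05, adjusted p = 0.990). Cyp2e1, the cytochrome that oxidises TCE, showed -0.27 log2 (SE 0.09, adjusted p = 0.0570), and -0.33 log2 (adjusted p = 0.00159) without BALB/cByJ vehicle replicate 2. Cyp2b10 (0.23 log2, adjusted p = 0.354), Cyp7a1, the first enzyme of bile acid synthesis (-0.02 log2, adjusted p = 0.977), and the proliferation marker Mki67 (-0.04 log2, adjusted p = 0.857) did not pass.

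In limma's test with strain and treatment groups and a batch term, 1350 of 19872 genes passed an adjusted p of 0.05, 760 higher and 590 lower with TCE. Of these, 35 changed at least 1.5-fold (30 higher, 5 lower), and 751 had the same sign in at least 13 strains. Without BALB/cByJ vehicle replicate 2 the count was 1926 (892 higher, 1034 lower), with 1270 genes called both ways. It was 816 without the batch term, 781 with ratios scaled between arrays, 3309 with array weights and 593 without FVB/NJ. Where arrays were only centred on their median, 1307 genes were higher and 107 lower, so the number of lower genes depended on the scaling.

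The second comparison asked which of 33 gene lists, fixed beforehand, shifted together. The list of PPAR-alpha targets (peroxisomal and omega-oxidation genes) rose most, by a mean of 0.50 log2 (SE 0.05, 94 arrays, higher in 14 of 16 strains), with a median gene at 0.24 log2. Of its 35 measured genes 21 rose and none fell over all genes tested, and 26 rose and none fell adjusted over the list alone. NRF2 targets, which serve glutathione and redox metabolism, rose by 0.27 log2 (SE 0.03, 15 strains). Of 27 genes 15 rose and 0 fell, or 17 and 1 adjusted over the list alone, among them Gsta2, Gsta1 (0.68 log2, SE 0.09), the sulfiredoxin gene Srxn1 (0.64 log2, SE 0.08) and Ugdh (0.50 log2, SE 0.06). The proteasome list rose by 0.16 log2 (SE 0.02, 13 strains). Of 30 subunit genes 25 rose and 0 fell, or 29 and 0 adjusted over the list alone, such as Psmd14 (0.31 log2, SE 0.05), Psmb5 (0.28 log2, SE 0.03) and Psmb6 (0.27 log2, SE 0.03). Mitochondrial fatty acid oxidation and ketogenesis rose by 0.14 log2 (SE 0.03, 14 strains). Of 26 genes 13 rose and 3 fell, or 15 and 4 adjusted over the list alone, with Crat at 0.46 log2 (SE 0.07), Eci1 at 0.38 log2 (SE 0.04) and Acad10 at -0.22 log2 (SE 0.04). Targets of p53 rose by 0.13 log2 (SE 0.03, 14 strains). Of 18 genes 7 rose and 0 fell, or 8 and 1 adjusted over the list alone, including the cell cycle inhibitor Cdkn1a (0.65 log2, SE 0.12), Aen (0.29 log2, SE 0.04), Mdm2 (0.21 log2, SE 0.03) and Bax (0.18 log2, SE 0.04). Oxidative phosphorylation genes stood at a mean of -0.12 log2 (SE 0.02, lower in 16 of 16 strains), but at 0.05 log2, not past the test, with arrays centred on their median. Of 37 genes 25 were lower and 0 higher, or 31 and 0 adjusted over the list alone, with the loess values. The complex II genes Sdhb and Sdha stood at -0.21 log2 (SE 0.03) and -0.25 log2 (SE 0.04), while the complex I gene Ndufa9, at -0.15 log2 (SE 0.03), changed sign to 0.02 log2 under that centring.

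The camera test gave these lists adjusted p-values of 1.24e-41 (PPAR-alpha), 2.66e-39 (proteasome), 2.68e-23 (oxidative phosphorylation), 2.89e-21 (NRF2), 3.34e-08 (mitochondrial oxidation) and 1.61e-07 (p53). They were also the 6 lists that held with an estimated correlation, at adjusted p = 0.000356, 0.000381, 0.0153, 0.000381, 0.0213 and 0.00512 in that order. With arrays centred on their median only 1 list held that way, and 5 with ratios scaled between arrays. Without BALB/cByJ vehicle replicate 2 mitochondrial oxidation did not hold (adjusted p = 0.0599 with an estimated correlation). Within batches, where the TCE and vehicle arrays came mostly from different strains, the mean of PPAR-alpha targets was 0.28, 0.41, 0.25, 0.75, 0.66 and 0.93 log2 in batches 1 to 6. The SE was 0.21, 0.17, 0.22, 0.21, 0.22 and 0.16 in that order. The range over batches was 0.16 to 0.39 log2 for NRF2 targets, 0.02 to 0.23 for the proteasome, 0.07 to 0.21 for mitochondrial oxidation, 0.07 to 0.20 for p53 targets and -0.22 to -0.08 for oxidative phosphorylation.

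**Figure D1:**
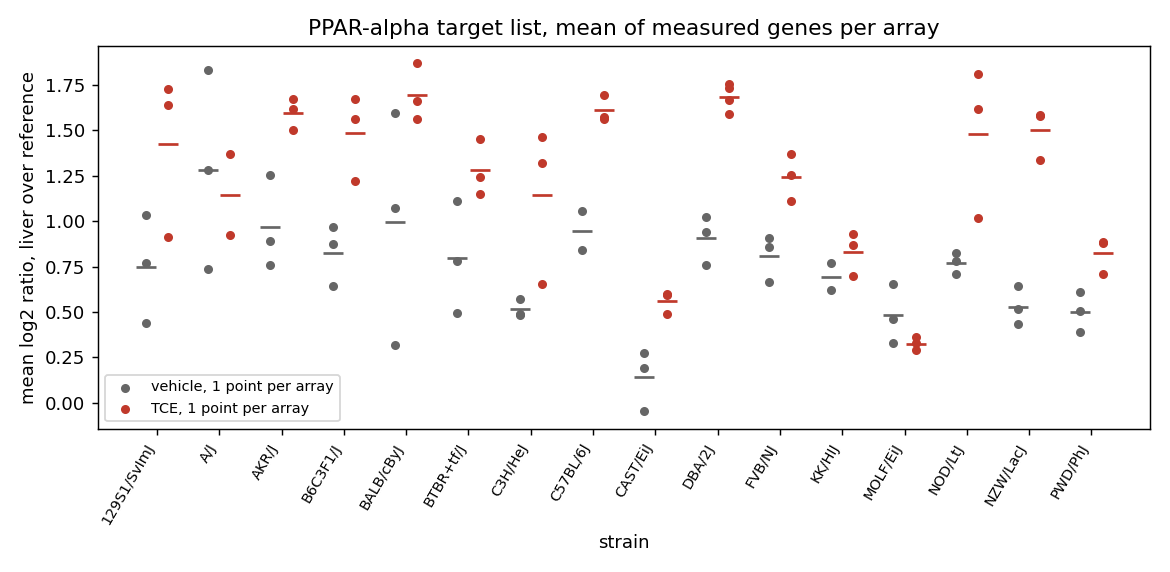
Mean log2 ratio of liver over the reference pool (vertical axis) for the measured genes of the PPAR-alpha target list on each array, by strain, with vehicle arrays in grey, TCE arrays in red and a dash at each group's mean. The TCE minus vehicle effect was highest in NZW/LacJ (0.97 log2) and lowest in MOLF/EiJ (-0.17 log2).

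With the preset correlation of camera, 14 lists passed, 7 higher and 7 lower, against 19 (6 higher, 13 lower) without BALB/cByJ vehicle replicate 2, 12 of them in both. The other 8 were lost with an estimated correlation. Ribosomal proteins stood at 0.05 log2 (adjusted p = 3.75e-06, and adjusted p = 0.430 with an estimated correlation). Of 39 genes 7 were higher and 0 lower, or 11 and 1 adjusted over the list alone, such as Rps19 and Rpl12 (0.17 and 0.15 log2). Acute phase genes stood at 0.17 log2 (adjusted p = 0.00104, and adjusted p = 0.645 with an estimated correlation). Of 27 genes 2 were higher, Il1rn (0.55 log2, SE 0.10) and Socs3 (0.40 log2, SE 0.13, ended by leaving out 1 array in 36 of 94 fits), also 2 adjusted over the list alone. Without BALB/cByJ vehicle replicate 2 that mean was 0.05 log2 and did not pass (adjusted p = 0.550). Male-biased liver genes stood at -0.19 log2 (adjusted p = 0.000135, and adjusted p = 0.317 with an estimated correlation). Of 21 genes 6 were lower, or 7 adjusted over the list alone, among them Hsd3b5, Selenbp2 (-0.44 log2) and Slco1a1 (-0.25 log2). Adipose markers stood at -0.26 log2 (adjusted p = 0.000135, and adjusted p = 0.283 with an estimated correlation), with 1 of 9 lower, or 5 adjusted over the list alone. Cholesterol synthesis stood at -0.16 log2 (adjusted p = 0.000315, and adjusted p = 0.645 with an estimated correlation). Of 25 genes 4 were lower, or 5 adjusted over the list alone, such as Idi1 (-0.48 log2, SE 0.14) and Cyp51 (-0.35 log2, SE 0.10). Pancreas markers stood at -0.08 log2 (adjusted p = 0.000981, and adjusted p = 0.589 with an estimated correlation), but at 0.07 log2 with arrays centred on their median. Of 13 genes 2 were lower, also adjusted over the list alone, Cpb1 (-0.32 log2) and Pnlip (-0.13 log2, but 0.02 log2 under that centring, and ended by leaving out 1 array in 51 of 94 fits). Cholangiocyte markers stood at -0.09 log2 (adjusted p = 0.0307, and adjusted p = 0.640 with an estimated correlation). Of 11 genes Sox9 was higher and Cldn7 lower (0.21 and -0.20 log2), or 1 higher and 2 lower adjusted over the list alone. Without BALB/cByJ vehicle replicate 2 that mean was -0.04 log2 (adjusted p = 0.178). Urea cycle and amino acid catabolism genes stood at -0.08 log2 (adjusted p = 0.0256, and adjusted p = 0.820 with an estimated correlation), but at 0.09 log2 with arrays centred on their median. With BALB/cByJ set aside, the mean without that centring was -0.56 log2 in strains with TCE mostly in batches 1 to 3 and 0.23 log2 in those with TCE mostly in batches 4 to 6 (unadjusted p = 0.0383, adjusted p = 0.281 over 33 lists), or -0.35 and -0.02 log2 where the fit left out BALB/cByJ vehicle replicate 2. Of 26 genes 3 were lower, also adjusted over the list alone, Ass1 (-0.37 log2), Got1 (-0.29 log2) and Asl (-0.19 log2). Leaving out 1 array ended the calls of the urea cycle list in 12 of 94 fits (mean down to -0.04 log2), of Sox9 in 19 and of Got1 in 13. The cholangiocyte call also ended without A/J TCE replicate 1 or vehicle replicate 3 of CAST/EiJ or replicate 2 of KK/HIJ or MOLF/EiJ (-0.08 log2 each). Without A/J TCE replicate 2 Asl (-0.16 log2), Rps19 (0.14 log2) and Idi1 (-0.45 log2) did not pass, nor did Idi1 without KK/HIJ vehicle replicate 2 (-0.42 log2). The other sign appeared within a batch for ribosomal proteins (-0.03 in batch 6), acute phase (-0.11 in batch 3), male-biased (0.05 in batch 1) and cholangiocyte genes (0.09 in batch 3). For cholesterol, pancreas and urea cycle it appeared in batch 4 alone (0.00067, 0.02 and 0.51 log2), and not without BALB/cByJ vehicle replicate 2 (-0.32, -0.09 and -0.08 log2). The adipose list kept its sign in each batch.

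The remaining 19 lists did not pass with all arrays. In the fit without BALB/cByJ vehicle replicate 2, 19 lists passed (6 higher, 13 lower), only 12 of them among the 14 above. The others were lists of this remaining set, each lower with TCE, bile acid transport and hepatocyte markers among them. Values below are with all arrays unless stated, so a list that does not pass below may be lower and pass in that fit. CAR and PXR targets, drug-metabolising genes, stood at 0.06 log2 (adjusted p = 0.104). Of 31 genes 6 rose, among them Aldh1a1 (0.53 log2, SE 0.14) and Cyp3a13 (0.43 log2, SE 0.12), and 8 rose and 3 fell adjusted over the list alone. The TCE metabolism list had a mean of -0.01 and a median of -0.10 log2 (adjusted p = 0.815). Of 21 genes 4 rose, Gstm1 (0.45 log2, SE 0.08) and Ephx1 (0.36 log2, SE 0.08) among them, and 1 fell, or 4 and 5 adjusted over the list alone. Heat shock genes had a mean of 0.0062 and a median of -0.06 log2, with the test's direction up (adjusted p = 0.610). Of 12 genes 4 rose, Hsp90aa1 (0.39 log2, SE 0.08) among them, and Dnajb1 (-0.19 log2, SE 0.05) fell, or 4 and 3 adjusted over the list alone. Lipogenesis stood at -0.03 log2 (adjusted p = 0.672), with 2 of 23 higher, Gpam and Acacb (both 0.34 log2), and 4 lower, or 3 and 5 adjusted over the list alone. Female-biased liver genes stood at 0.17 log2 (adjusted p = 0.135), with 4 of 22 higher and 2 lower, or 4 and 3 adjusted over the list alone. Their mean was -0.13 log2 in the 7 strains with TCE mostly in batches 1 to 3 and 0.46 log2 in the 8 with TCE mostly in batches 4 to 6, BALB/cByJ set aside (unadjusted p = 0.00598, adjusted p = 0.197 over 33 lists). Gluconeogenesis and fasting genes stood at -0.05 log2 (adjusted p = 0.135), with 0 of 13 higher and 1 lower, or 1 and 4 adjusted over the list alone. The unfolded protein and ATF4 response stood at -0.0018 log2 (adjusted p = 0.972), with Atf3 (0.38 log2) and Psat1 (0.30 log2) higher of 22 and 1 lower, the same counts adjusted over the list alone.

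Bile acid and sterol transport had a mean of 0.01 and a median of -0.02 log2 (adjusted p = 0.603), with Abcc2 (0.23 log2) higher and Slco1a1 lower of 21, also 1 and 1 adjusted over the list alone. Without BALB/cByJ vehicle replicate 2 its mean was -0.09 log2 and passed (adjusted p = 0.0345, and adjusted p = 0.263 with an estimated correlation). AhR targets stood at 0.02 log2 (adjusted p = 0.603), with Nqo1 (0.37 log2, SE 0.08) the 1 gene of 7 that rose, also adjusted over the list alone. The circadian clock list stood at -0.08 log2 (adjusted p = 0.0788), with Bhlhe40 (-0.20 log2) the 1 of 21 that fell and 0 adjusted over the list alone. The interferon response stood at -0.04 log2 (adjusted p = 0.294), with Ifit3 (-0.16 log2) the 1 of 28 that fell, also adjusted over the list alone. Macrophage markers stood at 0.06 log2 (adjusted p = 0.135), with Cd68 (0.37 log2, SE 0.07) higher and Lyz2 (-0.15 log2) lower of 18, also 1 and 1 adjusted over the list alone. Limma called 0 genes, also adjusted over the list alone, among markers of hepatocytes (-0.0033 log2, adjusted p = 0.904), endothelium (-0.02, adjusted p = 0.366), lymphocytes (-0.03, adjusted p = 0.344), neutrophils (0.04, adjusted p = 0.603), and stellate cells and fibroblasts (-0.02, adjusted p = 0.786). Erythroid markers (-0.17 log2, adjusted p = 0.0601) and the cell cycle list (-0.02 log2, adjusted p = 0.672) also had 0 genes. Hepatocyte markers stood at -0.15 log2 and passed without BALB/cByJ vehicle replicate 2 (adjusted p = 0.000117, and adjusted p = 0.250 with an estimated correlation).

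The third comparison asked which genes TCE changed by different amounts in different strains. Of the genes named for such dependence, Car3, a carbonic anhydrase, had the largest effect in 1 strain, in FVB/NJ, at -4.44 log2 (SE 0.62, n = 3 and 3, adjusted p = 2.82e-06), though the deposited value table gave -1.44 log2, not past the test. In DBA/2J, with 4 TCE and 3 vehicle arrays, the glutathione transferases Gsta2 and Gsta1 rose by 3.64 log2 (SE 0.45) and 3.39 log2 (SE 0.40), and Cyp2a4 by 3.10 log2 (SE 0.50). Srxn1 rose there by 2.13 log2 (SE 0.33) and the mannose metabolism gene Pmm1 by 2.00 log2 (SE 0.30), while the guanylate-binding protein gene Gbp8 fell by 2.37 log2 (SE 0.35). In FVB/NJ the methyltransferase gene Inmt, the pyrimidine-degrading Dpyd, the interferon-induced Gbp4 and the chemokine gene Cxcl10 fell by 2.47 (SE 0.31), 2.07 (SE 0.34), 1.75 (SE 0.31) and 1.49 log2 (SE 0.34). Nol3 (2.47 log2, SE 0.47) and Nucb2 (1.964 log2, SE 0.32) rose there, and Chrdl2 was at least 4.59-fold higher, since its vehicle arrays lay at background. Strain dependence also passed for Cstb and Cebpd (1.61 and 1.35 log2 in DBA/2J, SE 0.30 each), Angptl4 (1.11 in NOD/LtJ and -1.40 in CAST/EiJ), Epha2 (1.30 in BTBR+tf/J) and Tbx3 (1.31 in KK/HIJ).

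The limma F test over the 15 strain differences passed for 112 of 19872 genes, and for 274 without BALB/cByJ vehicle replicate 2, which included all of the 112. Of the 112, 75 were also called in the averaged comparison. The count rested on DBA/2J, with 4 genes left without that strain, and it ranged from 43 without DBA/2J vehicle replicate 3 to 775 without KK/HIJ vehicle replicate 1, a fit that leaves that group 1 array, assumed to vary like the other groups. It was 43 without the batch term and 27 with ratios scaled between arrays. Leaving out 1 array ended the strain dependence of Car3 in 72 of 94 fits, of Epha2 in 63, Tbx3 in 55, Dpyd in 46, Cxcl10 in 37, Nucb2 in 7 and Nol3 in 4. Without DBA/2J vehicle replicate 2 or 3 it ended for Srxn1 and Pmm1.

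Within single strains, FVB/NJ and DBA/2J had the most genes past the adjusted threshold. Cyp4a14 rose 19.3-fold in FVB/NJ (4.27 log2, SE 1.11, n = 3 and 3, adjusted p = 0.00933) and 33.3-fold in DBA/2J (5.06 log2, SE 1.12, n = 4 and 3, adjusted p = 0.00499), though neither passed in the deposited value table. In FVB/NJ 1450 genes passed, 614 higher and 836 lower, with Car3 the largest fall. In DBA/2J 396 passed, 253 higher and 143 lower, with the crystallin gene Crybb3 the largest fall at -2.60 log2 (SE 0.42). Both strains shared 139 called genes, of which 92 were higher in both and 43 lower in both, against 7.82 and 6.02 that independent lists would share. The lists are not independent, since both tests used the same residual spread of each gene. Part of the excess could arise from that, and it is not specific to these strains where TCE acts in most strains. The FVB/NJ count was 748, 605 and 712 without its vehicle replicate 1, TCE replicate 2 and vehicle replicate 2, and Cyp4a14 did not pass there without vehicle replicate 3 (3.71 log2). The DBA/2J count was 255, 190 and 170 without its vehicle replicates 1, 2 and 3, 226 and 221 without its TCE replicates 1 and 3 (replicate 3 being 1 of the 2 from batch 5), and 801 without BALB/cByJ vehicle replicate 2.

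Few genes passed in 6 other strains. At an unadjusted p under 0.05 BALB/cByJ had 3053 genes, more than the 2502 of DBA/2J and fewer than the 3903 of FVB/NJ, and KK/HIJ had 2030, C3H/HeJ 1616, NZW/LacJ 1273, MOLF/EiJ 745 and PWD/PhJ 350. A share of about 0.05 of the 19872 genes would reach such a p with no effect, and the counts of MOLF/EiJ and PWD/PhJ lay under it. The BALB/cByJ number includes vehicle replicate 2, the array that stood apart, and was not counted without it. KK/HIJ had 37 genes (29 higher, 8 lower), among them the stress gene Ddit4 at -1.41 log2 (SE 0.30). In NZW/LacJ 7 genes passed (6 higher, 1 lower), with Acot1 at 2.72 log2 (SE 0.54) and Zfp637 at -0.77 log2 (SE 0.15). In BALB/cByJ 5 passed (2 higher, 3 lower), led by the lipid droplet gene Plin2 at 1.86 log2 (SE 0.35) and the dynein gene Dnah17 at -1.98 log2 (SE 0.40). PWD/PhJ had 5 (1 higher, 4 lower), MOLF/EiJ 2 (both higher) and C3H/HeJ 1 (higher). The adenylate cyclase gene Adcy10 stood at 1.45 log2 (SE 0.25) in MOLF/EiJ and -1.25 log2 (SE 0.23) in PWD/PhJ, but lay at background in 21 of 32 groups. Each of these named calls ended when certain single arrays were left out. Ddit4 did not pass without KK/HIJ vehicle replicate 2, TCE replicate 2 or 3 (-1.18, -1.28 and -1.47 log2), or Zfp637 without NZW/LacJ vehicle replicate 1, TCE replicate 1 or 2 (-0.25, -0.74 and -0.77 log2). Acot1 did not pass without any 1 NZW/LacJ array or BALB/cByJ vehicle replicate 1 (2.47 to 3.02 log2). Plin2 did not pass without BALB/cByJ vehicle replicate 2 (1.005 log2), its TCE replicate 1 or 3 (1.64 and 1.962 log2), or vehicle replicate 1 of FVB/NJ or NZW/LacJ (1.83 log2 both). Dnah17 did not pass without BALB/cByJ TCE replicate 1 or 3 (-1.20 and -1.502 log2), vehicle replicate 1 of C3H/HeJ, FVB/NJ or NZW/LacJ, or PWD/PhJ TCE replicate 1 (-2.02 to -1.97 log2). Its fall was larger without BALB/cByJ TCE replicate 2 (Dnah17: TCE effect in BALB/cByJ, -3.19 log2). Adcy10 did not pass without MOLF/EiJ TCE replicate 2 (1.07 log2) or PWD/PhJ TCE replicate 1, vehicle replicate 1 or 3 (-1.03, -1.21 and -1.12 log2). The count of KK/HIJ was 2604 without its vehicle replicate 1 and 10 without its replicate 2, but each of these fits leaves 1 vehicle array, assumed to vary like the other groups, so neither shows how wide its response is. It was 149 without its TCE replicate 1 and 2 without its TCE replicate 3, and that of BALB/cByJ 2921 and 2783 without its vehicle replicates 1 and 3. Both of these BALB/cByJ fits keep vehicle replicate 2, the array that stood apart, as 1 of 2 vehicle arrays. Without replicate 2 that strain had 1 gene.

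Limma called 0 genes in the other 8 strains, where the number at an unadjusted p under 0.05 was 1607 in 129S1/SvImJ, 1114 in C57BL/6J, 684 in A/J, 550 in B6C3F1/J, 539 in NOD/LtJ, 362 in AKR/J, 280 in BTBR+tf/J and 242 in CAST/EiJ. With no effect, a share of about 0.05 of the 19872 genes would reach such a p. The counts of A/J and of the strains listed after it lay under that share. Without 129S1/SvImJ vehicle replicates 2 or 3 that strain had 127 or 220 genes. The median over 16 strains was 0.5 genes, and 1 without BALB/cByJ vehicle replicate 2, where FVB/NJ had 1925, DBA/2J 801 and BALB/cByJ 1. With arrays centred on their median DBA/2J had 7773 and FVB/NJ 731, with ratios scaled between arrays FVB/NJ had 465, and with array weights they had 7352 and 6169. With the deposited value table DBA/2J had 252, and 46 where that table also lacked BALB/cByJ vehicle replicate 2 and 6 columns, 2 of them DBA/2J TCE arrays.

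**Figure D2:**
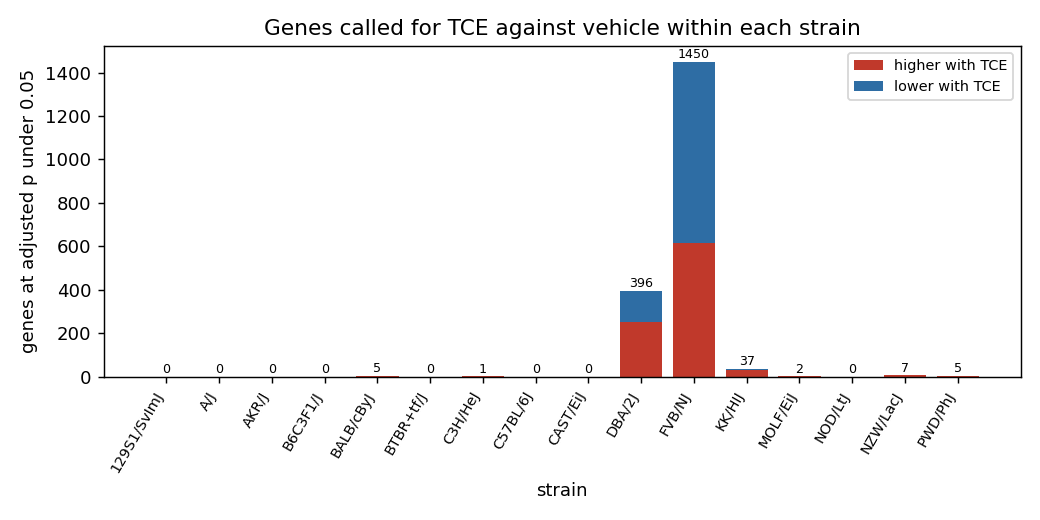
Number of genes past an adjusted p of 0.05 for TCE against vehicle within each strain (horizontal axis, strains; vertical axis, number of genes), stacked as higher and lower with TCE and with the total on top. FVB/NJ had 1450 and DBA/2J 396, and 8 strains had 0.

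The fourth comparison asked whether the lists shifted by different amounts between strains. NRF2 targets rose most in DBA/2J, by 0.96 log2 (SE 0.14, n = 4 and 3, adjusted p = 1.45e-07), and by 0.51 log2 in B6C3F1/J (SE 0.15), and stood at -0.02 log2 in NOD/LtJ. The proteasome list rose by 0.55 log2 in DBA/2J (SE 0.10) and 0.47 log2 in FVB/NJ (SE 0.09). Heat shock genes went both ways: they rose by 0.63 log2 in DBA/2J (SE 0.14) and fell by 0.48 log2 in FVB/NJ (SE 0.14) and 0.50 log2 in BALB/cByJ (SE 0.14). The BALB/cByJ value includes vehicle replicate 2, the array that stood apart, and how far it rests on that array is not given here. Removing the array moved the batch 4 mean of this list from -0.32 to -0.25 log2. That mean covers 8 TCE and 6 vehicle arrays of several strains, so it does not show the change in BALB/cByJ. Ribosomal proteins rose by 0.43 log2 in FVB/NJ (SE 0.09).

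PPAR-alpha targets rose by 0.97 log2 in NZW/LacJ (SE 0.22, n = 3 and 3, adjusted p = 0.000688), 0.78 in DBA/2J, 0.73 in NOD/LtJ and 0.72 in BALB/cByJ, the last at 0.42 log2 without vehicle replicate 2. Means were near 0 in KK/HIJ, A/J and MOLF/EiJ (0.12, -0.10 and -0.17 log2). In limma's F test on list means, 4 of 33 lists depended on strain: proteasome (adjusted p = 0.00143), heat shock (adjusted p = 0.00486), NRF2 (adjusted p = 0.00953) and ribosomal proteins (adjusted p = 0.0404). PPAR-alpha targets stood at adjusted p = 0.0892. Leaving out 1 array ended the call of ribosomal proteins in 29 of 94 fits, and that of NRF2 targets without DBA/2J vehicle replicate 3 (adjusted p = 0.0679). Without BALB/cByJ vehicle replicate 2 these 4 and 5 more passed: PPAR-alpha (adjusted p = 0.0210), CAR and PXR targets (adjusted p = 0.00515), bile acid transport (adjusted p = 0.0273), interferon response (adjusted p = 0.0247) and TCE metabolism (adjusted p = 0.0344). In that fit, with BALB/cByJ set aside, the CAR and PXR list stood at -0.23 log2 in the 7 strains with TCE mostly in batches 1 to 3 and 0.20 log2 in the 8 with TCE mostly in batches 4 to 6 (unadjusted p = 0.00610, adjusted p = 0.201 over 33 lists), so its dependence on strain and a difference between batches are not separated. The count of 4 was 2 with ratios scaled between arrays or without DBA/2J vehicle replicate 3, 7 with arrays centred on their median, 27 with array weights, 13 without BALB/cByJ vehicle replicate 1 and 15 without its replicate 3. The last 2 fits keep vehicle replicate 2, the array that stood apart, as 1 of 2 BALB/cByJ vehicle arrays.

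**Figure D3:**
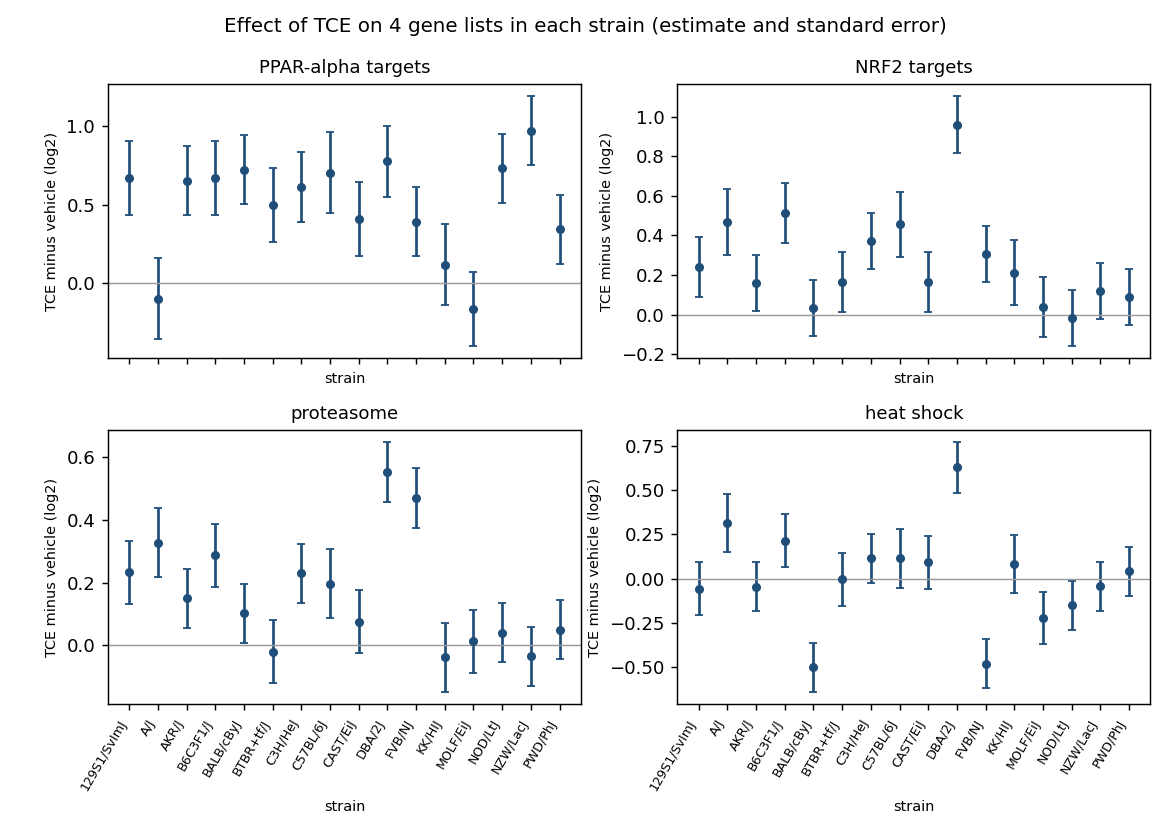
TCE minus vehicle mean log2 effect (estimate and SE) of 4 gene lists in each of 16 strains, in panels for PPAR-alpha targets, NRF2 targets, the proteasome and heat shock. DBA/2J was highest for NRF2 targets (0.96 log2), the proteasome (0.55 log2) and heat shock (0.63 log2).

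The last comparison asked how vehicle livers differed between strains. Cyp4a14 spanned a wide range, from 4.52 ± 1.5 log2 in A/J (SD, n = 3) to -3.54 ± 0.66 log2 in CAST/EiJ (SD, n = 3). Akr1c18, a steroid dehydrogenase, stood at 3.84 ± 0.10 log2 in PWD/PhJ and -2.62 ± 0.25 in 129S1/SvImJ (SD, n = 3 each). The melanin enzyme gene Dct stood at 5.09 ± 0.43 in DBA/2J and -2.01 ± 0.64 in 129S1/SvImJ. Cav1, of caveolae, stood at 1.15 ± 0.27 log2 in MOLF/EiJ and -5.75 ± 0.15 in A/J, and Nnmt, nicotinamide N-methyltransferase, at 2.43 ± 0.41 in CAST/EiJ and -2.66 ± 0.38 in A/J. The sulfotransferase gene Sult3a1 stood at 8.11 ± 0.46 log2 in CAST/EiJ and lay at background in 11 of 16 vehicle groups, and Sult2a2 stood at 7.75 ± 0.15 in PWD/PhJ and lay at background in 7. Other genes among the widest were Wfdc21 (2.79 in NZW/LacJ, -3.90 in PWD/PhJ), the interferon-induced Iigp1 (2.34 in NZW/LacJ, -4.87 in CAST/EiJ), and Moxd1 (4.28 in MOLF/EiJ, -1.33 in A/J). They also included Nat8f5 (2.78 in MOLF/EiJ, -3.23 in BTBR+tf/J), Ptprg (-0.12 in C57BL/6J, -4.48 in PWD/PhJ), E2f8 (3.61 in DBA/2J, -1.97 in MOLF/EiJ) and the glutathione transferase Mgst2 (2.69 in PWD/PhJ, -1.91 in A/J).

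The limma F test passed for 13198 of 19872 genes (66.4%), and for 13253 without BALB/cByJ vehicle replicate 2. Sult3a1, Sult2a2, Wfdc21 and the olfactory receptor gene Olfr1153 did not pass without the 3 wild-derived strains, where the SD of their vehicle means was 0.19, 0.19, 0.65 and 0.21 log2. A strain's sequence variants under a probe change its signal too, so a difference in level and one in hybridisation cannot be separated on these arrays.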

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

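The tests of the single array that stands apart and of the concentration of calls in FVB/NJ and DBA/2J were chosen after the results were seen, and the shuffles of the treatment and strain labels were planned.

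The TCE effect differed between strains, in an F test of that difference itself, for genes and lists that include these. For genes with their most extreme effect in DBA/2J the adjusted p was 0.000920 for Gsta2, 0.00208 for Gsta1, 0.00832 for Srxn1, 0.0104 for Pmm1, 0.00807 for Cyp2a4, 0.00628 for Cstb, 0.00628 for Cebpd and 0.000920 for Gbp8. For those with it in FVB/NJ it was 0.0482 for Car3, 0.00119 for Inmt, 0.0431 for Dpyd, 0.00490 for Gbp4, 0.0421 for Cxcl10, 0.0172 for Nol3, 0.000920 for Chrdl2 and 0.0305 for Nucb2. It was 0.00496 for Angptl4, 0.0473 for Epha2 and 0.0461 for Tbx3, whose most extreme strains were others. Leaving out 1 array ended the call of Car3 in 72 of 94 fits, Epha2 in 63, Tbx3 in 55, Dpyd in 46, Cxcl10 in 37, Nucb2 in 7, Nol3 in 4 and Srxn1 and Pmm1 in 2 each. Among the lists it was 0.00143 for the proteasome, 0.00486 for heat shock, 0.00953 for NRF2 targets and 0.0404 for ribosomal proteins, a call that leaving out 1 array ended in 29 of 94 fits.

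In the 4 DBA/2J TCE arrays, the single group large enough for the test, 1 array lay far from the other 3 for 7 of 155 values, where chance gives about 1 in 20. The gap over the range (Dixon's ratio) was 0.963 for Acot2, 0.874 for Ehhadh, 0.834 for Mpv17l, 0.891 for Myom2, 0.881 for Plin2, 0.841 for Psmb5 and 0.915 for the bile acid transport list. The array apart was replicate 1 in 1 case, replicate 2 in 2, replicate 3 in 3 and replicate 4 in 1.

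FVB/NJ and DBA/2J held most of the genes called within a strain, 1450 and 396, where the next strain, KK/HIJ, had 37, though DBA/2J had 46 with the deposited value table without 6 columns, 2 of them its own, and BALB/cByJ vehicle replicate 2. With any 1 of their own arrays left out they had at least 170 genes, and without the batch term at least 569, which argues against a single array or the fitted term as the whole cause, but not against a difference between batches, since no batch held both DBA/2J arms and only batch 1 both FVB/NJ arms, so batch and TCE cannot be told apart in DBA/2J beyond what other strains show of the batches. The SD of their effects was at least 1.40 times the median of the 16 strains, where a smaller spread with effects of the usual size predicted an SD at or below that median. The fit gave all groups 1 residual spread per gene, though, so a smaller spread of their own arrays could not lower their SE. The SD therefore decides nothing on that explanation. A high SD is not particular to them, since 129S1/SvImJ (1.32) and KK/HIJ (1.30) also had a high SD, with 0 and 37 genes. BALB/cByJ (1.62, 5 genes) had the highest, but its vehicle arrays include the array that stood apart. For FVB/NJ the real assignment gave the most genes of 10, 1450 against 2 for the next, but 10 assignments are too few to decide, and in DBA/2J 2 of 35 assignments gave as many, so chance is not excluded, and the higher one, with 802 genes, set the batch 6 TCE array among the 3 vehicle arrays. A response of these strains beyond that of the others stays open as a hypothesis, untested on other mice.

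BALB/cByJ vehicle replicate 2 stood apart from the other arrays. Against the 2 other BALB/cByJ vehicle arrays, its 12 measured hepatocyte markers had a median of -6.11 log2 (SE of the mean 0.60), with Alb at -4.59, Apoa1 at -5.86 and Ttr at -4.58. Only 1 of them, Hnf4a, was higher (0.26 log2). The median argues against a mixture with at least 50% liver RNA. The share of Cy5 spots well above background, 68.3%, lay within the 42.4% to 79.5% of the other arrays, which argues against a failed hybridisation. A candidate explanation is kidney RNA in place of liver RNA: the median of 29 measured kidney markers was 4.199 log2 higher (SE of the mean 0.37), all 29 were higher, Kap, abundant in male kidney, by 7.64 log2, and the highest other organ list, testis, stood at 0.22 log2. All 29 were also above background on most other arrays and 1 is in a list fixed earlier, and the array still correlated best with its own strain (0.463), so a wrong organ of the right strain remains a hypothesis for which no second measurement exists.

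Among 100 shuffles of the treatment labels within strains, the real ones included, only the real labels gave as many as 1350 averaged genes (highest other 860) and as many as 6 lists with an estimated correlation (highest other 2). Chance is thus unlikely for both, though 100 shuffles cannot exclude it. For lists dependent on strain, 2 of 100 gave as many as 4 (highest other 4). A shuffle thus matched the real labels, so chance is unlikely there but not excluded. Chance is not excluded for strain dependence of genes, where 5 of 100 gave as many as 112. The highest other count was 759, and its source was not tested. Chance is also not excluded for the median of 0.5 genes per strain (17 of 100, highest other 1). Nor is it excluded for the 14 lists with the preset correlation (34 of 100, highest other 20). Among 100 shuffles of strain labels over the vehicle arrays, only the real ones gave as many as 13198 genes (highest other 5095) or 20 lists (highest other 14). Chance is thus unlikely there too, though again not excluded by 100 shuffles. Of the 10 assignments within a strain, too few to decide, 7 gave as many as the 5 genes of BALB/cByJ (highest other 2102), 4 as many as the 1 of C3H/HeJ (highest other 2) and 3 as many as the 2 of MOLF/EiJ (highest other 4). Of 10 again, 2 gave as many as the 7 of NZW/LacJ (highest other 159), 4 as many as the 5 of PWD/PhJ (highest other 8) and 1, the real one, the 1450 of FVB/NJ (highest other 2). What gave the high counts in BALB/cByJ and NZW/LacJ was not tested, and BALB/cByJ vehicle replicate 2 was kept in each assignment.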

How the results depend on the processing

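The fits without BALB/cByJ vehicle replicate 2 and the batch block together, without the 4 arrays of largest residual spread, and from the value table without 6 columns and BALB/cByJ vehicle replicate 2 were chosen after the results were seen. The number of genes that differed between strains in vehicle liver stayed within 1.5 times of 13198 under each alternative run (12819 to 14024 with 1 array left out), and so did the 14 shifted lists, except as given here. Of the averaged effects of named genes under the alternatives that kept all strains or left out a fixed set, 1495 kept direction and side of the threshold, 94 fell short of it, 36 passed it, 2 changed sign and 23 moved untested. Signal over background limits what can be called: dim genes shrink towards 0 with the offset. Where no cause is named below, the cause was not tested.

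Without the batch block, the averaged effect had 816 genes (499 higher, 317 lower), strain dependence 43 and the median strain 2. Without the block and BALB/cByJ vehicle replicate 2, the median strain had 3 genes, 7 lists depended on strain, and bile acid transport stood at -0.09155 log2. Scaling between arrays gave 781 averaged genes (510 higher, 271 lower), 27 strain-dependent genes, 0 in the median strain and 2 strain-dependent lists. Array weights, which ran from 0.0326 for BALB/cByJ vehicle replicate 2 to 9.16 for DBA/2J TCE replicate 2, gave 3309 (1418 higher, 1891 lower), 10856, 75 and 27. The 1.5-fold minimum left 35 (30 higher, 5 lower), by its construction. The share of averaged calls that were higher was 56.3%, but 71.9% (1234 higher, 482 lower) with the Agilent processed ratio, 69.3% (908 and 403) with Cy5 alone, and 42.9% with array weights. It was 92.4% (1307 and 107) with median centring, which moved the median of all genes from -0.0075 to 0.050 log2.

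Strain dependence had 224 genes with the Agilent processed ratio, 231 with no background subtraction, 209 with Cy5 alone, and 67 with the deposited value table. It had 47 with that table without 6 columns and BALB/cByJ vehicle replicate 2, 61 without the batch 5 array titled DBA/2JTCE_5, 50 without the wild-derived strains (fewer arrays) and 319 without the 4 arrays of largest residual spread. The median strain had 1.5 genes with the Agilent processed ratio, 6.5 with no background subtraction, 3 with Cy5 alone, 2 without the 3 arrays of the other protocol, and 2.5 without the 4 arrays of largest residual spread. It had 0 with median centring, the value table, detection on at least 90% of arrays or no wild-derived strains. The number of strain-dependent lists was 7 with median centring and 9 without the 4 arrays of largest residual spread.

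With median centring Ndufa9 stood at 0.02476, Pnlip at 0.02419, and the lists of oxidative phosphorylation at 0.05468, pancreas at 0.06812 and urea cycle at 0.08851 log2, each with the other sign. An estimated correlation left 6 shifted lists, 5 with the Agilent processed ratio, scaling, Cy5 alone, the value table or array weights, and 1 with median centring. Batch 1 alone gave 6 (3 higher, 3 lower). Within batches most strains differ between treatments, and batch 4 holds BALB/cByJ vehicle replicate 2. Signs turned there for lists that passed in neither the averaged nor the batch fit, not given here, and for these that passed in at least 1: cholangiocyte 0.03266 and male-biased 0.05143 in batch 1, acute phase -0.1144, cell cycle 0.0645 and cholangiocyte 0.08518 in batch 3, and acute phase -0.02699 and cell cycle 0.07659 in batch 5. In batch 4 they were cholesterol 0.0006661, heat shock -0.3162, hepatocyte 0.8309, interferon 0.4937, lymphocyte 0.1629, pancreas 0.01516, ribosomal -0.009696, TCE metabolism 0.3511 and urea cycle 0.5121 log2. These turns in batch 4 were gone without BALB/cByJ vehicle replicate 2 for cholesterol (-0.3153), hepatocyte (-0.0833), pancreas (-0.09485), ribosomal (0.008784), TCE metabolism (-0.0216) and urea cycle genes (-0.07747), and stayed for heat shock (-0.2451), interferon (0.3155) and lymphocyte (0.02719). Ribosomal proteins stood at -0.0306 in batch 6, acute phase at -0.002115, cell cycle at 0.05023 and cholangiocyte at 0.03586 in batches 1 to 3, and interferon at 0.2465 and urea cycle at 0.01814 in batches 4 to 6. As a plain difference of means acute phase stood at 0.001611 (SE 0.1156) in batches 1 to 3, so its sign there is not settled. In such a difference over batches 4 to 6 without BALB/cByJ vehicle replicate 2, the urea cycle turn was gone (-0.1727) and that of interferon stayed (0.1743).

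With 1 array or strain left out, the averaged effect had 593 genes (without FVB/NJ) to 1926 (without BALB/cByJ vehicle replicate 2), and strain dependence 4 (without DBA/2J) to 775 (without KK/HIJ vehicle replicate 1). A fit without 1 of the 2 arrays of a group assumes that the lone array left varies like the other groups. The median strain had 0 to 2.5 (46 arrays moved it over 1.5 times), strain-dependent lists 2 to 15, shifted lists 12 to 19, and bile acid transport -0.09278 (without BALB/cByJ) to 0.05885 log2 (without BALB/cByJ vehicle replicate 3). Single arrays that moved strain dependence over 1.5 times were, in DBA/2J, vehicle replicates 3 (43) and 2 (46) and TCE replicates 3 (61) and 1 (65), and in FVB/NJ, vehicle replicates 2 (46), 3 (54) and 1 (66) and TCE replicate 2 (52). The others were BALB/cByJ TCE replicate 3 (72) and vehicle replicates 2 (274), 1 (306) and 3 (473), KK/HIJ TCE replicate 2 (73) and vehicle replicate 1 (775), and C3H/HeJ TCE replicate 1 (179). For strain-dependent lists they were DBA/2J vehicle replicate 3 (2) and BALB/cByJ vehicle replicates 2 (9), 1 (13) and 3 (15). The fits without BALB/cByJ vehicle replicate 1 or 3 keep replicate 2, which stood apart, as 1 of 2 vehicle arrays of that group.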

Other observations

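The tests of batch in A/J and of the F1 hybrid were chosen after the results were seen, and so was the choice of which list levels in vehicle liver to describe. The tests of the Y-linked genes and of the relations across strains were written before their results.

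Vehicle livers differed between strains in the level of 20 of 33 gene lists. Heat shock genes were 0.79 log2 above the mean of strains in FVB/NJ (SE 0.09, n = 3) and -0.34 log2 from it in A/J (SE 0.09, n = 3; adjusted p = 2.48e-10). Interferon response genes were 0.70 log2 above it in DBA/2J (SE 0.13) and at -0.42 in 129S1/SvImJ (SE 0.14; adjusted p = 1.47e-06). Circadian clock genes ran from 0.49 in FVB/NJ (SE 0.10) to -0.40 log2 in C57BL/6J (SE 0.12; adjusted p = 3.64e-05). PPAR-alpha targets ran from 0.54 in A/J (SE 0.15) to -0.60 log2 in CAST/EiJ (SE 0.16; adjusted p = 0.00875). With BALB/cByJ, which holds the array that stood apart, set aside, macrophage markers ran from 0.61 in C57BL/6J (SE 0.16) to -0.40 log2 in NOD/LtJ (SE 0.13). Their adjusted p was 8.02e-07 with all arrays and 4.38e-07 without BALB/cByJ vehicle replicate 2. Erythroid markers ran from 0.63 in 129S1/SvImJ (SE 0.15) to -0.61 in PWD/PhJ (SE 0.14; adjusted p = 0.000123). Hepatocyte and stellate cell markers were among the 20 but did not pass without BALB/cByJ vehicle replicate 2 (adjusted p = 0.472 and 0.0554).

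B6C3F1/J is the F1 hybrid of C57BL/6J and C3H/HeJ, and its vehicle liver lay between its parents more often than that of other strains for genes that set them apart. The parents differed in 515 genes, 290 higher in C57BL/6J and 225 higher in C3H/HeJ (n = 2 and 3 arrays). Genes picked for a wide gap place many strains inside it, 50.9% to 64.5% of these genes for the 13 other strains (median 55.7%). The hybrid's mean (n = 3) lay between them in 438, or 85.0%, with a median position of 0.428 on a scale from 0 (C3H/HeJ) to 1 (C57BL/6J). Cyp4a14 was 5.52 log2 higher in C57BL/6J than in C3H/HeJ (SE 1.24, adjusted p = 0.00303), the thyroid hormone deiodinase Dio1 3.81 (SE 0.41), Ptprg 3.79 (SE 0.30), Nat8f5 3.70 (SE 0.56) and Nnmt 3.61 log2 (SE 0.63). The hybrid differed from the mean of its parents in 557 genes. For the TCE effect limma called 0 genes between the hybrid and that mean (922 at an unadjusted p under 0.05) and 0 between the parents (328 at an unadjusted p under 0.05). Both unadjusted counts lay under the share of about 0.05 of the 19872 genes that no effect would give.

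A/J vehicle livers were low in male-biased and high in female-biased genes. The lists stood at -1.003 (SE 0.17) and 0.78 log2 (SE 0.13) from the mean of strains (n = 3), with 12 of 21 male-biased genes lower and 0 higher, such as Mup1 at -2.48 (SE 0.54) and Cyp7b1 at -2.15 log2 (SE 0.37), and 8 of 22 female-biased genes higher and 1, Ntrk2, lower (-0.76 log2), led by Cyp4a14 (4.14 log2, SE 0.74), which with Acot3 (2.04 log2) is also among the genes that TCE raised. The 4 measured Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had a mean log2 ratio of 0.72 over the 5 A/J arrays, inside the 0.39 to 2.12 of the other 89, which argues against female mice under this label. A/J TCE arrays, run in other batches, stood at -0.75 (SE 0.22, adjusted p = 0.0101) and 1.09 log2 (SE 0.17, adjusted p = 4.96e-07) from the mean of TCE groups, which argues against a batch of the vehicle arrays. A trait of the A/J strain, or of these mice, may account for it and remains a hypothesis.

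Across the 16 strains, the level of Cyp2e1 or Ppara in vehicle liver was set against the TCE effect on 2 lists, 4 relations in all, with permutation p-values from 100000 resamples. Cyp2e1 gave r = 0.161 with PPAR-alpha targets (p = 0.552, adjusted p = 0.555; rho = 0.218, p = 0.416, adjusted p = 0.554), and 0.185 without the 2 strains farthest from the median, 129S1/SvImJ and FVB/NJ. With NRF2 targets it gave r = 0.162 (p = 0.555, adjusted p = 0.555; rho = 0.159, p = 0.555, adjusted p = 0.555), and 0.209 without those strains. Ppara gave r = 0.436 with PPAR-alpha targets (p = 0.0908, adjusted p = 0.182; rho = 0.471, p = 0.0681, adjusted p = 0.273), and 0.414 without PWD/PhJ and DBA/2J. With NRF2 targets it gave r = 0.499 (p = 0.0530, adjusted p = 0.182; rho = 0.365, p = 0.163, adjusted p = 0.326), and 0.178 without PWD/PhJ and DBA/2J. In the 8 strains with TCE in batches 1 to 3 and the 8 others, r was -0.05 and 0.48, 0.51 and 0.25, 0.43 and 0.44, and 0.53 and 0.66 in the order above. None passed, and the rule written beforehand, that an adjusted p of 0.05 or more speaks against a relation, was wrong: over 16 strains such a p leaves even r = 0.499 open.

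In the deposited value table, with each probe's mean over arrays subtracted, 6 columns correlated more with another array's scanner values than with those of their own array, while all 94 scanner files were closest to their own strain. The columns were C3H/HeJ vehicle replicate 1, CAST/EiJ TCE replicate 1 and vehicle replicate 3, MOLF/EiJ TCE replicate 1, and DBA/2J TCE replicates 1 and 2. Their correlation with their own array ran from -0.13 for the MOLF/EiJ column to 0.51 for DBA/2J TCE replicate 2 after that subtraction. Before it, the range was 0.797 to 0.937, with 0.881 for the MOLF/EiJ column.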
